A study of Homo sapiens with 4 samples.

How the data were processed

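Native poly(A) RNA was measured in 4 libraries of HEK293T cells, a human embryonic kidney-derived line, with 1 library for each of 4 groups. Cells received control or LARP1 siRNA for 42 hours and were then given DMSO or Torin1 at 250 nM. Per the labels' protocols, abundant small capped RNAs were depleted by lithium chloride precipitation, capped RNA was bound on beads carrying a cap-binding eIF4E variant, and the eluted RNA was sequenced directly on a nanopore device. Either of a pair of kit versions was used, and which library had which is not given in the sources used here. The duration of the Torin1 treatment is not given either.

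The deposited table holds raw counts of reads per gene symbol, 1 column per library, with the length of each gene's merged exons as a further column, per the file headers. Reads were aligned with minimap2 2.15 to hg38 and counted with featureCounts of Subread 1.6.2, per the submitters' processing notes. The settings for strand, multi-mapping and overlapping genes are not given in the sources used here, so genes that overlap another on either strand, and genes with pseudogenes, may have gained or lost reads to them. All 57133 symbols of the table occur in GENCODE release 29, and 56981 had the same span there. Coordinates are those of the table on hg38, counted from 1. Transcript length, GC content and A content of each gene came from the GENCODE 29 transcripts as medians over the gene's transcripts, and all 8839 tested genes had them. A read of this kind is a native RNA molecule without amplification. Counting intervals and floors cover counting error only.

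Totals were 799497 counts in control siRNA with DMSO, 851653 in control siRNA with Torin1, 890244 in LARP1 siRNA with DMSO and 860922 in LARP1 siRNA with Torin1. A count of 0 allows up to 3 counts, which is 3.75, 3.52, 3.37 and 3.48 CPM in these libraries. Genes with a mean of at least 10 counts over the 4 libraries were tested. They numbered 8839 of 18846 genes with any count and held 97.5% of all counts. Libraries were scaled by TMM factors (edgeR 4.0.16), and 0.5 was added to each count before a log2 ratio.

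Each group holds 1 library, so no comparison between a pair of groups has a replicate check. For each of the 4 comparisons a gene was called higher or lower when the exact conditional binomial test of its 2 counts (2-sided, Benjamini-Hochberg over genes, threshold 0.05) passed and the fold was at least 1.5. This test compares those libraries, not the conditions, and its p-values are not printed. Log2 ratios carry exact 95% binomial counting intervals, and shares of a library's counts exact (Clopper-Pearson) 95% binomial intervals. The difference of the Torin1 effects (LARP1 siRNA minus control siRNA) carries a Wald 95% interval from counting error. A model with siRNA and agent as additive terms (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) has 1 residual degree of freedom, which holds the difference of the Torin1 effects. It is the sole test in which libraries are the replicates, and "rose" and "fell" are used for its calls. Its gene-wise spread was pooled over all genes, so a gene that stands apart in a single library can pass it. Nothing says that libraries came from separate cultures, so its p-values measure the spread between these libraries.

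The 19 gene lists, the tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size drawn from the 100 genes nearest each member in mean count. Only the list's own members were left out of these, so the random lists of a TOP list could hold other TOP genes. A list is said to stand apart below the 2.5 or above the 97.5 percentile, as a description of these libraries. Named genes were LARP1, then the 10 highest and 10 lowest called genes of each comparison by the interval bound nearest no change, the 5 highest and 5 lowest for the difference of the Torin1 effects, and up to 4 members per list with the most counts. Members of a list that passed the additive test are also named where 5 or fewer did, and these were chosen after their values were seen.

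Alternatives were totals, DESeq2 size factors, upper-quartile factors or TMM without TOP and mitochondrial genes for scaling; count minimums of 2.5, 25 or none; thinning to the smallest total; no fold minimum or 2; an assumed biological coefficient of variation of 0.2 or 0.4; other random lists; a gene length trend taken off; list means; genes with a mean of at least 50 counts or genes outside the TOP lists for correlations; and DESeq2 1.42.0 or no covariate for the additive model. Alternatives chosen after seeing the data were length and GC trends taken off, fitted on all genes or on genes outside the TOP lists and pseudogenes, pseudogene counts added to their parent genes, random lists outside TOP genes and pseudogenes, and counts without mitochondrial DNA genes. No library could be left out.

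The callers were tested on simulated data. For Torin1 in control siRNA, with 8839 genes, the pair caller recovered 25 of 97 genes changed by a log2 fold of 1 and 80 of 100 changed by 2, with 4 false calls. The additive test on Torin1 recovered 39 of 100 and 88 of 100 at those sizes over the same 8839 genes, with 6 false calls at a simulated coefficient of variation of 0.15. For Torin1 in control siRNA, a list shifted by 0.5 was recovered at 0.52 among 8839 genes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3.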

Results

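The data are counts of native, cap-purified poly(A) RNA molecules in HEK293T cells, a human kidney-derived line, read with nanopore direct RNA sequencing. The design crosses a knockdown with a drug. Control or LARP1 siRNA was given for 42 hours, followed by DMSO, the solvent, or Torin1, an inhibitor of the mTOR kinase, at 250 nM. LARP1 is an RNA-binding protein that recognises TOP mRNAs, whose sequence starts with a run of pyrimidines and which encode ribosomal proteins and translation factors. The title of the series asks how mTOR and LARP1 act on the poly(A) tails and ribosome loading of these mRNAs. Tail lengths and ribosome loading are not analysed here. The counts give the abundance of cap-purified poly(A) RNA molecules relative to the others of a library. Each of the 4 groups holds 1 library, with 799497 to 890244 counts, so differences between groups have no replicate check. The libraries detected 14523 (control siRNA, DMSO), 15266 (control siRNA, Torin1), 15056 (LARP1 siRNA, DMSO) and 15279 (LARP1 siRNA, Torin1) genes.

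LARP1 itself (chromosome 5, 154712902 to 154817607) was read first, as a check of the labels. It had 278 counts in control siRNA with DMSO, 280 in control siRNA with Torin1, 75 in LARP1 siRNA with DMSO and 68 in LARP1 siRNA with Torin1. LARP1 siRNA lowered it 4.71-fold under DMSO (log2 -2.23, 95% counting interval -2.63 to -1.87) and 4.50-fold under Torin1 (log2 -2.17, -2.58 to -1.79). In the additive model LARP1 fell by 2.21 on the log2 scale (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.49e-15), lower in both pairs of libraries. Under Torin1 the LARP1 level differed from DMSO by less than counting error, with log2 -0.15 (-0.39 to 0.10) in control siRNA and -0.09 (-0.58 to 0.41) in LARP1 siRNA.

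The comparison of Torin1 with DMSO in control-siRNA cells asks what mTOR inhibition did to capped mRNAs with LARP1 present. Genes of glucose use, amino acid supply, lipid synthesis, ribosome assembly and protein folding were lower, while the TOP lists had medians above 0. DDIT4, a stress-induced inhibitor of mTOR signalling, went from 269 to 34 counts (log2 -3.13, -3.70 to -2.63). The hexokinase HK2 was 8.97-fold lower (log2 -3.17, -4.05 to -2.45) and the glucose transporter SLC2A1 7.32-fold lower (log2 -2.87, -3.58 to -2.27). STC2 (log2 -2.70) and the transferrin receptor TFRC (log2 -2.32) were also among the lowest. So were HMOX1, heme oxygenase, at log2 -2.80, and MT-RNR1, the small mitochondrial ribosomal RNA, at -2.39. BATF3 went from 21 counts to 0 and was at least 7.82-fold lower. The highest genes were 5 mitochondrial mRNAs, described with the other mitochondrial RNAs at the end, and 5 nuclear genes. Among these, ACTA2, smooth muscle actin, went from 8 to 63 counts (log2 2.74, 1.75 to 4.09), SNHG7, a snoRNA host, from 35 to 191 (log2 2.27, 1.76 to 2.85), and INPP5D, an inositol phosphatase, from 1 to 26 (log2 3.98, 1.93 to 9.90). ZNF280B went from 0 to 21 counts, at least 6.27-fold higher. MAP9 also rested on few counts, going from 1 to 23 counts (log2 3.81, 1.74 to 9.73).

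Grouped by the fixed lists, 12 of 18 measured glycolysis and hypoxia-factor genes were lower and 0 higher in control siRNA (median log2 -1.31; 95% of random lists, -0.36 to 0.26; percentile 0.00). LDHA, which makes lactate, was at -1.77 and the glycolytic enzyme ENO1 at -1.45. Of 30 ATF4 targets, which supply amino acids and charged tRNAs, 22 were lower and 0 higher (median -0.98, percentile 0.00), with the serine synthesis enzyme PSAT1 at -2.02 and the amino acid transporter SLC7A5 at -2.16. Of 29 SREBP-driven sterol and fatty acid genes, 17 were lower and 0 higher (median -0.84, percentile 0.00), including FASN, fatty acid synthase, at -1.20. Ribosome assembly factors had 16 of 32 lower (median -0.77, percentile 0.00), among them NOLC1 at -1.01 and NHP2 at -1.10. Chaperones had 17 of 23 lower (median -0.66, percentile 0.02), with HSP90AA1 at -1.23. Mitochondrial ribosomal proteins (20 of 58 lower, 1 higher, median -0.46, percentile 0.00) and nuclear respiratory chain subunits (18 of 61 lower, 0 higher, median -0.41, percentile 1.51) stood apart too. The respiratory chain list no longer did with length and GC trends or a gene length trend taken off, or against lists matched on gene length. The median of the FOXO targets was 0.60 (6 higher, 2 lower of 16, percentile 99.75), with the cell cycle inhibitor CDKN1B at 0.97 and TSC22D3, lower, at -0.67. Mitosis genes had a median of 0.23 (4 higher, 2 lower of 23, percentile 99.83), with TOP2A, a topoisomerase, at 0.81. They no longer stood apart with length and GC trends taken off, nor did FOXO targets with a gene length trend taken off.

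The TOP mRNAs are the transcripts named in the title of the series. Large-subunit ribosomal protein mRNAs had a median of 0.17 under Torin1 in control siRNA (2 higher, 1 lower of 44, percentile 99.96), and the other protein-coding TOP mRNAs 0.23 (2 higher, 1 lower of 22, percentile 99.83; no longer apart at 0.13 with a gene length trend taken off and 0.20 with length and GC trends fitted outside TOP genes taken off). Small-subunit ribosomal protein mRNAs had a median of 0.06 (1 higher, 1 lower of 30, percentile 71.12) and did not stand apart, although they did against random lists without TOP genes and pseudogenes, chosen after seeing the data (95% of these, -0.59 to -0.11). The non-coding TOP snoRNA hosts had a median of 0.92 (7 higher, 0 lower of 11, percentile 100.00), with GAS5 at 0.79 and SNHG1 at 1.57. Torin1 in control siRNA gave 637 genes higher and 870 lower of 8839, but 771 and 724 with totals and 739 and 748 with upper-quartile factors, so which direction has more genes depends on the scaling.

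**Figure D1:**
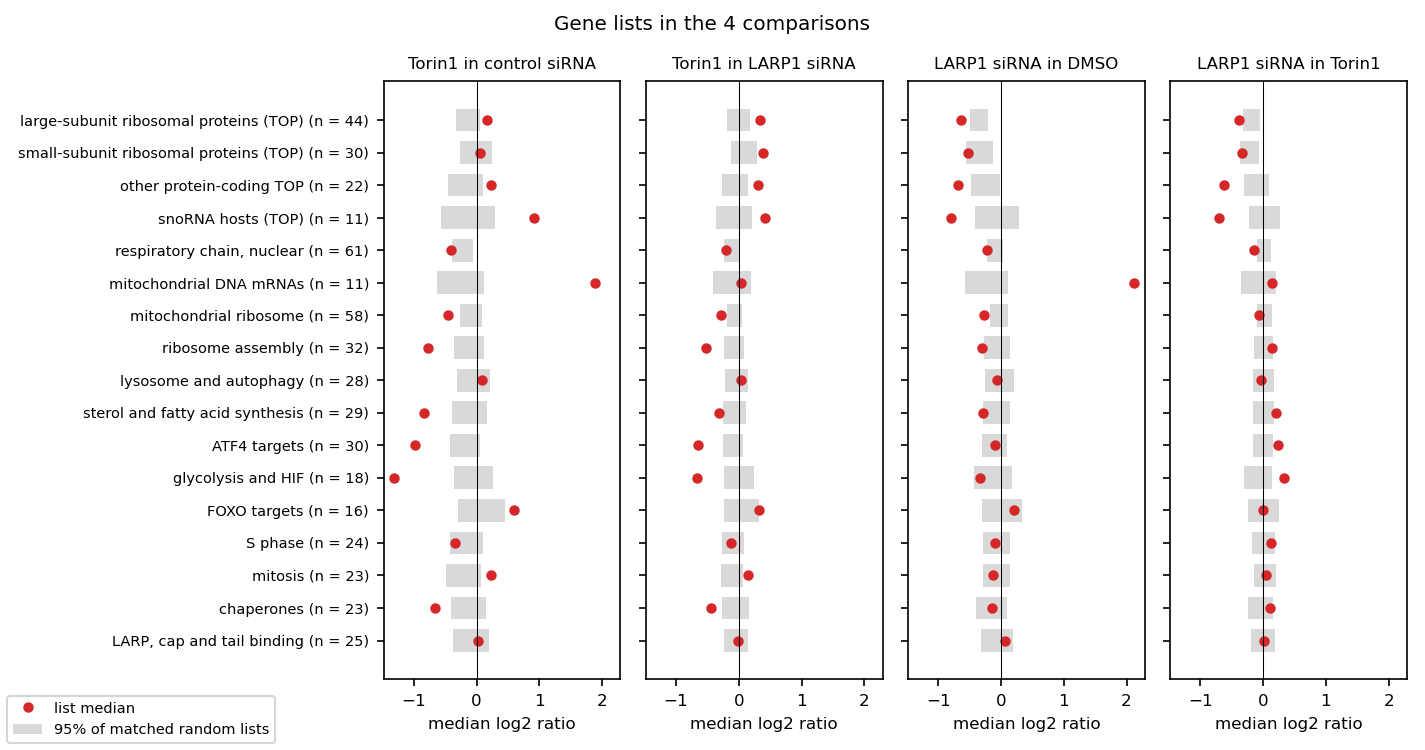
Median log2 ratio (x axis) of the measured members of each gene list (y axis, n = members) in the 4 comparisons, with 1 library per group; red points are list medians and grey bars hold 95% of 10000 random lists matched on mean count. Glycolysis lies at -1.31 and ATF4 targets at -0.98 for Torin1 in control siRNA, and the TOP lists lie between -0.79 and -0.34 in both LARP1 siRNA comparisons.

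In LARP1-siRNA cells, the comparison of Torin1 with DMSO asks the same with LARP1 depleted. The metabolic genes were again lower, by less. HK2 was 2.53-fold lower (log2 -1.34, -1.83 to -0.88), TFRC 2.37-fold (log2 -1.24, -1.59 to -0.92), LDHA was at log2 -1.08, PSAT1 at -1.15 and MT-RNR1 at -1.70. SDF2L1, an endoplasmic reticulum chaperone partner, was at -1.48, PTGES3, a co-chaperone, at -0.97 with 5 pseudogenes of its name, JMJD6 at -1.68, PPARGC1B at -1.83 and FHOD1 at -1.76. Lists with the lowest medians were glycolysis (-0.66, 8 of 18 lower), ATF4 targets (-0.65, 15 of 30), ribosome assembly (-0.52, 6 of 32), chaperones (-0.44, 6 of 23 lower, 1 higher), SREBP genes (-0.32, 6 of 29) and mitochondrial ribosomal proteins (-0.28, 5 of 58), each below percentile 2.5. The nuclear respiratory chain list was at -0.21 (percentile 4.60). The medians of the TOP lists were above 0, each above percentile 99, although most members were not called. They were 0.34 for large-subunit proteins (4 higher, 0 lower of 44), 0.38 for small-subunit proteins (5 of 30), 0.31 for other TOP mRNAs (1 of 22) and 0.42 for snoRNA hosts (3 of 11). RPS18 (log2 0.70) was among the ribosomal protein mRNAs called higher.

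The highest genes in LARP1-siRNA cells under Torin1 included DHRS2, a dehydrogenase (1 to 45 counts, log2 4.98, 2.99 to 10.88), ACTA2 (4 to 39, log2 3.19) and BMF, a cell death factor (3 to 27, log2 3.03, 1.52 to 5.59). MAP9 went from 1 to 17 counts (log2 3.60, 1.47 to 9.53). Others were RB1CC1 (log2 3.51), GCC2 (2 to 24 counts, 3.35, 1.63 to 6.77), ATRX (2.95), GOLGB1 (2.62), CENPF (2.34), ASPM (2.33) and KTN1 (1.99). These had their lowest counts in the LARP1-siRNA DMSO library, such as 27 for CENPF against 126, 182 and 134 in the other libraries. Mitosis genes had a median of 0.15 (5 higher, 0 lower of 23, percentile 99.68) and FOXO targets 0.33 (2 of 16 higher, percentile 97.58). In all, 302 genes were higher and 304 lower (374 and 233 with upper-quartile factors).

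Over both siRNA arms, 269 genes rose and 305 fell with Torin1 in the additive model (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ATF4 targets fell in 17 of 30 cases (25 adjusted over the list alone), glycolysis genes in 11 of 18 (14 adjusted over the list alone), ribosome assembly genes in 11 of 32 (21), SREBP genes in 9 of 29 (12), chaperones in 8 of 23 (12), mitochondrial ribosomal proteins in 8 of 58 (9) and nuclear respiratory chain genes in 7 of 61 (12). DDIT4 fell by 1.95 on the log2 scale (edgeR adjusted p = 5.98e-11), HK2 by 2.10 (2.73e-10) and LDHA by 1.42 (5.93e-08), each lower in both arms. Of the FOXO targets 4 rose and 1 fell of 16, the same as adjusted over the list alone; TXNIP, KLHL24, SESN3 and CDKN1B rose and CITED2 fell. GAS5, SNHG1, SNHG7 and EPB41L4A-AS1 rose among 11 snoRNA hosts (6 adjusted over the list alone), and TOP2A, HMMR, CENPE and CENPF among 23 mitosis genes (4). Of these mitosis genes TOP2A and HMMR were called higher in both arms, while CENPE and CENPF were not. The rise of CENPF rests largely on its low count in the LARP1-siRNA DMSO library. Large-subunit ribosomal protein mRNAs had 0 of 44 past the edgeR test in either direction (0 adjusted over the list alone), with 10 higher and 0 lower at an unadjusted p under 0.05 and 0 by DESeq2. RPS27 rose and RPS26 fell among 30 small-subunit mRNAs (1 and 1 adjusted over the list alone), and VIM rose and EEF1D fell among 22 other TOP mRNAs (2 and 1). DESeq2 with the same design called 9 genes higher and 36 lower. By list it called 5 ATF4, 5 glycolysis, 3 SREBP, 2 chaperone and 1 respiratory chain genes lower, and 1 mitosis gene higher. Those lists had 20, 8, 10, 14, 41 and 13 members with an adjusted p. It called 0 ribosome assembly, mitochondrial ribosome, FOXO and snoRNA host genes, with 12, 12, 0 and 4 such members. Across 8839 genes, which are not independent replicates, the Torin1 effects in the arms, which share no library, had a Pearson correlation of 0.40 and a Spearman correlation of 0.39 (simulated unchanged libraries, 0.004 and 0.001). In both arms 98 genes were called higher and 171 lower, against 21.8 and 29.9 for independent lists. Those figures take every gene as equally likely to be called. Calls favour genes with many counts, which alone raises the overlap, and no figure matched on counts was made.

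**Figure D2:**
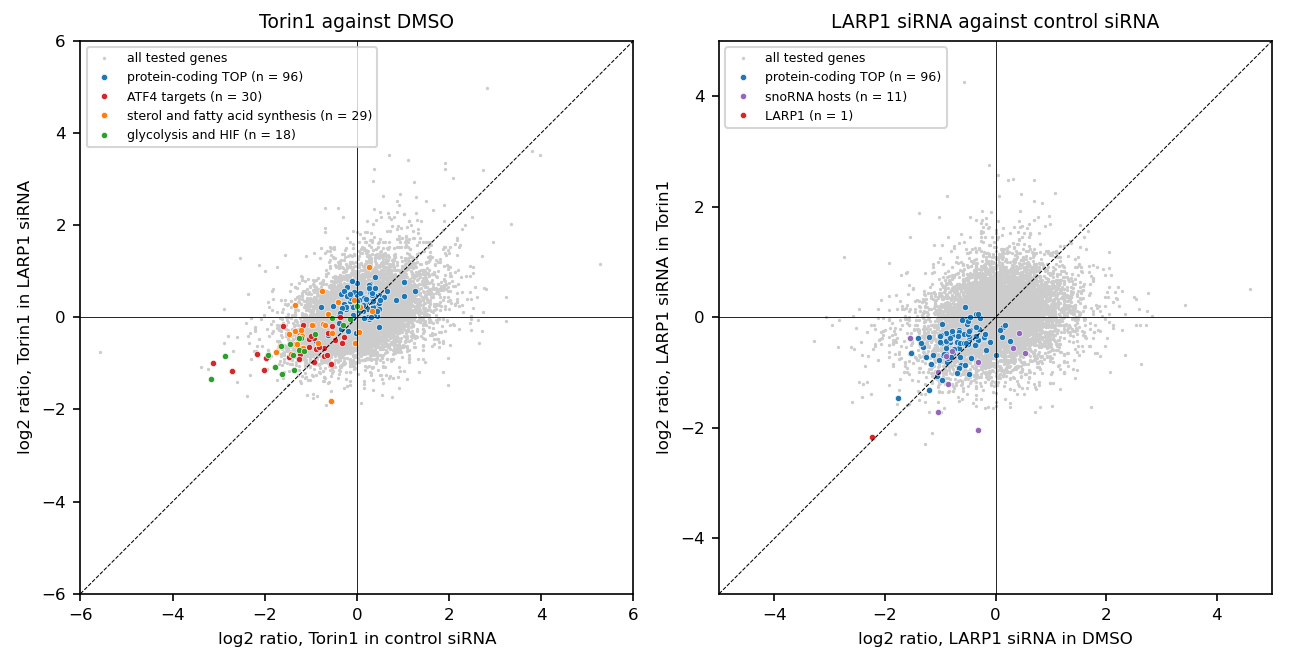
Log2 ratio of each of 8839 tested genes (points) for Torin1 against DMSO in control siRNA (x) and LARP1 siRNA (y), left, and for LARP1 siRNA against control siRNA under DMSO (x) and Torin1 (y), right, with 1 library per group; colours mark gene lists and the dashed line is equality. The metabolic lists lie below 0 in both arms and nearer 0 on the y axis (ATF4 medians -0.98 and -0.65), and LARP1 lies at -2.23 and -2.17.

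LARP1 siRNA against control siRNA under DMSO asks what depletion of LARP1 did with mTOR active. Of the 4 TOP lists, 3 stood apart below 0. Large-subunit ribosomal protein mRNAs had a median log2 ratio of -0.64 (23 lower, 0 higher of 44; percentile 0.11; -0.33 and no longer apart with length and GC trends of all genes taken off), other protein-coding TOP mRNAs -0.68 (14 lower, 0 higher of 22; percentile 0.06) and snoRNA hosts -0.79 (3 lower, 0 higher of 11; percentile 0.00). A bootstrap over the 11 snoRNA hosts ran from -1.03 to 0.32 and spans 0. Small-subunit ribosomal protein mRNAs had a median of -0.52 (13 lower, 0 higher of 30; percentile 3.98) and did not stand apart, although they did against random lists without TOP genes and pseudogenes, chosen after seeing the data (95% of these, -0.32 to 0.08). EEF2, the translocating elongation factor, was 2.38-fold lower (log2 -1.25, -1.31 to -1.19), and NPM1, nucleophosmin, 2.30-fold lower (log2 -1.20), with 45 pseudogenes of its name that may share its reads. EEF1A1 (log2 -0.83) and RPS19 (log2 -0.61) were lower, while RPL10 (log2 0.11, 19 pseudogenes of its name) and RPS2 (log2 0.17, 20 pseudogenes) were not called. Ribosomal proteins took 13.10% of the counts in LARP1 siRNA with DMSO (exact binomial 95% interval 13.03% to 13.17%) and 16.94% in control siRNA with DMSO (16.85% to 17.02%).

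The lowest genes under DMSO besides LARP1 included PGM1, a sugar phosphate mutase (log2 -2.37, -2.97 to -1.83), CENPF (-2.55), PHF3 (-2.43), the pseudogene NPM1P6 (-2.40), NEFM, a neurofilament protein (-2.13) and HMOX1 (-2.07). The highest nuclear genes were TOB1, an antiproliferative factor (9 to 81 counts, log2 2.75, 1.82 to 4.00), NUDT19 (8 to 61, log2 2.50) and ZNF280B (0 to 15, at least 3.92-fold higher). HMOX1, NEFM, TOB1, NUDT19 and ZNF280B each had counts in control siRNA with DMSO apart from those of the other 3 libraries. Mitochondrial ribosomal proteins had a median of -0.27 (11 of 58 lower, percentile 0.15) and ribosome assembly factors -0.30 (6 lower, 1 higher of 32, percentile 1.18). The metabolic lists did not stand apart, with medians of -0.10 for ATF4 targets, -0.29 for SREBP genes (percentile 2.56) and -0.33 for glycolysis. In all, 364 genes were higher and 578 lower. With totals in place of TMM factors these became 793 and 294, as that scaling raised the median of all genes by 0.20.

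Under Torin1, LARP1 siRNA against control siRNA asks whether depletion of LARP1 mattered with mTOR inhibited. The same 3 TOP lists stood apart below 0. The medians were -0.39 for large-subunit ribosomal protein mRNAs (9 lower, 0 higher of 44; percentile 0.04), -0.63 for other TOP mRNAs (12 lower, 0 higher of 22; percentile 0.00) and -0.70 for snoRNA hosts (7 lower, 0 higher of 11; percentile 0.00). For small-subunit mRNAs the median was -0.34 (5 lower, 0 higher of 30; percentile 10.40) and did not stand apart, although it did against random lists without TOP genes and pseudogenes (95% of these, -0.13 to 0.16). RPL13A was 2.75-fold lower (log2 -1.46, -1.72 to -1.21), NPM1 was at -1.31, SNHG1 at -1.71 and SNHG7 at -2.03. EIF1, a start-codon selection factor (log2 -1.44), ATP5F1C, an ATP synthase subunit (-1.56), CAMLG (-1.65), ZNF277 (-2.08) and TAF1D (-1.65) completed the lowest genes. Of the 10 highest genes, 6 were called lower with Torin1 in control siRNA, a comparison that shares the control-siRNA Torin1 library, so that this library alone favours opposite signs. They were DDIT4 (2.83-fold higher, log2 interval 0.95 to 2.12), SLC7A5 (log2 1.49, 1.06 to 1.95), ATAD3B (1.61), TNIP2 (10 to 43 counts), BATF3 (0 to 10, at least 3.03-fold higher) and HSPA1B at 2.23 (1.51 to 3.11), a heat shock protein with a near-identical neighbour HSPA1A that may share its reads. The others were RNF4 at 2.24, IMMP2L (4 to 29 counts), ABHD11 (2 to 18, log2 2.75, 0.97 to 6.18) and DUSP8 (3 to 21, log2 2.48, 0.93 to 5.06).

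The metabolic lists lay above 0 between the Torin1 libraries, with medians of 0.34 for glycolysis (3 higher, 0 lower of 18, percentile 100.00), 0.24 for ATF4 targets (4 higher, 1 lower of 30, percentile 99.85) and 0.21 for SREBP genes (4 higher, 1 lower of 29, percentile 99.09). These metabolic lists were low with Torin1 in control siRNA, which shares the control-siRNA Torin1 library, so that library alone favours values above 0. The nuclear respiratory chain list was at -0.14 (4 lower, 1 higher of 61, percentile 0.65). In all, 139 genes were higher and 246 lower. With totals these became 292 and 163, as that scaling raised the median of all genes by 0.12.

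Over both agents, 45 genes rose and 118 fell with LARP1 siRNA in the additive model (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 69 and 33 with totals). TOP mRNAs fell in 11 of 44 cases for the large subunit (24 adjusted over the list alone), 7 of 30 for the small subunit (13), 8 of 22 for other TOP mRNAs (18) and 6 of 11 for snoRNA hosts (6). In edgeR 0 members of these lists rose, and 0 were higher at an unadjusted p under 0.05, with 31, 14, 18 and 7 lower. DESeq2 called 7, 4, 5 and 0 lower and 0 higher, and gave an adjusted p for 40, 25, 16 and 3 of them. RPL13A fell by 1.61 on the log2 scale (edgeR adjusted p = 1.21e-08), NPM1 by 1.25 (3.95e-06), EEF2 by 0.99 (0.000574) and GAS5 by 1.02 (0.00407), each lower under both agents. Outside these lists, ATP5F1C fell by 1.67 (edgeR adjusted p = 3.84e-09) and NDUFA10 by 0.97 among 61 respiratory chain genes (1 rose and 4 fell adjusted over the list alone), and ATF4 by 0.87 (0.0125) among 30 ATF4 list genes (1 and 2). Of 23 chaperones HSPA1B rose while HSPA8 and HSP90AB1 fell (2 and 4 adjusted over the list alone). GPI rose by 0.95 among 18 glycolysis genes (1 adjusted over the list alone), and CENPF fell by 1.38 among 23 mitosis genes (2). CENPF was not called lower under Torin1, and its fall rests largely on its low count in the LARP1-siRNA DMSO library. DESeq2 with the same design called 0 genes higher and 31 lower, with 217 genes at an unadjusted p under 0.05, against 1080 in edgeR. The LARP1 siRNA effects under the agents share no library, and had a Pearson correlation of 0.23 and a Spearman correlation of 0.24 across 8839 genes (simulated, 0.003 and -0.000). Under both agents 20 genes were called higher and 90 lower, against 5.72 and 16.1 for independent lists, figures that again take every gene as equally likely to be called.

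The difference of the Torin1 effects asks whether the response to mTOR inhibition depended on LARP1. It has no replicate check, and all 4 libraries enter each value. Among nuclear lists the medians farthest above 0 were those of SREBP genes (median 0.70, 14 of 29 with a counting interval above 0 and 0 below, percentile 100.00), glycolysis (0.56, 10 of 18 above and 0 below, percentile 99.99) and ATF4 targets (0.41, 12 of 30 above and 0 below, percentile 99.88), whose Torin1 effects were less negative with LARP1 siRNA. Ribosome assembly (0.30, percentile 99.07) and mitochondrial ribosome (0.23, percentile 98.54) lists also stood apart, while the respiratory chain (0.19, percentile 85.89) and chaperone (0.19, percentile 75.87) lists did not. The mitochondrial ribosome list no longer did with length and GC trends or a gene length trend taken off, or against lists matched on gene length. DDIT4 (difference 2.12, 1.51 to 2.73) and HMOX1 (2.38, 1.58 to 3.18) were among the highest genes, with NOP9 (3.27, 1.69 to 4.85) and LENG1 (3.82, 1.66 to 5.98) on few counts. The lowest were MT-CYB (-2.68), MT-ND3 (-2.80), MT-ND4 (-2.63), MT-ND2 (-2.45) and MT-ND1 (-1.84). Small-subunit ribosomal protein mRNAs had a median of 0.33 (18 above, 5 below of 30, percentile 99.14), while the large-subunit list (0.19, percentile 61.89) and other TOP mRNAs (0.09, percentile 24.97) did not stand apart. With a gene length trend taken off, the small-subunit median was 0.15 and no longer stood apart. SnoRNA hosts had a median of -0.50 (1 above, 3 below of 11, percentile 0.07), with a bootstrap over members of -0.87 to 0.18, which spans 0. In all, 885 genes had a counting interval above 0 and 611 below. In 3451 genes with a mean of at least 50 counts, the slope of the Torin1 effect in LARP1 siRNA on that in control siRNA was 0.43 after counting noise was taken out. Other spread between the control-siRNA libraries stays in and lowers this slope, so it does not measure how much smaller the response was. Without counting noise, the standard deviation of the Torin1 effects was 0.56 in control siRNA and 0.35 in LARP1 siRNA.

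Most mRNAs made from mitochondrial DNA, which carry no cap, set the control-siRNA DMSO library apart from the other 3. Mitochondrial mRNAs took 0.28% of its counts (exact binomial 95% interval 0.27% to 0.29%), against 0.89% (0.87% to 0.91%) in control siRNA with Torin1, 0.96% (0.94% to 0.98%) in LARP1 siRNA with DMSO and 1.05% (1.03% to 1.07%) in LARP1 siRNA with Torin1. MT-ND4 had 168, 1263, 1443 and 1504 counts in these libraries in that order, and MT-CYB 185, 1272, 1372 and 1267. The median of 11 mitochondrial mRNAs was therefore 1.89 for Torin1 in control siRNA and 2.12 for LARP1 siRNA under DMSO (percentile 100.00 in both), but 0.03 for Torin1 in LARP1 siRNA and 0.14 for LARP1 siRNA under Torin1. MT-ND6 went the other way, with 312 counts in control siRNA with DMSO and 47, 69 and 45 in the others; it lies on the opposite strand to the other mitochondrial mRNAs, and whether strand was used in counting is not stated. MT-ND1, MT-ND2 and MT-ND3 were also higher, at log2 2.12, 2.48 and 3.25 for Torin1 in control siRNA, and MT-ATP6 and MT-CO2 at 2.24 and 1.81 for LARP1 siRNA under DMSO. The transfer RNAs MT-TP (46, 5, 12 and 5 counts) and MT-TS1 (45, 12, 9 and 9) were highest in the control-siRNA DMSO library as well. Not all followed this: MT-CO1 had 484, 592, 673 and 862 counts and the ribosomal RNA MT-RNR2 846, 1259, 1745 and 1633, and MT-RNR1 (635, 135, 1036 and 306) split DMSO from Torin1 instead, falling by 2.03 on the log2 scale with Torin1 (edgeR adjusted p = 2.9e-14). In the additive edgeR test 6 of 11 mitochondrial mRNAs rose and 1 fell with Torin1 (9 and 1 adjusted over the list alone), and 8 rose and 1 fell with LARP1 siRNA (8 and 1), although a single library stands apart. DESeq2 called 0 of them for either factor, with 10 at an unadjusted p under 0.05 in edgeR for each. That library is the baseline of both Torin1 in control siRNA and LARP1 siRNA under DMSO, including the gene groups given above for them.

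**Figure D3:**
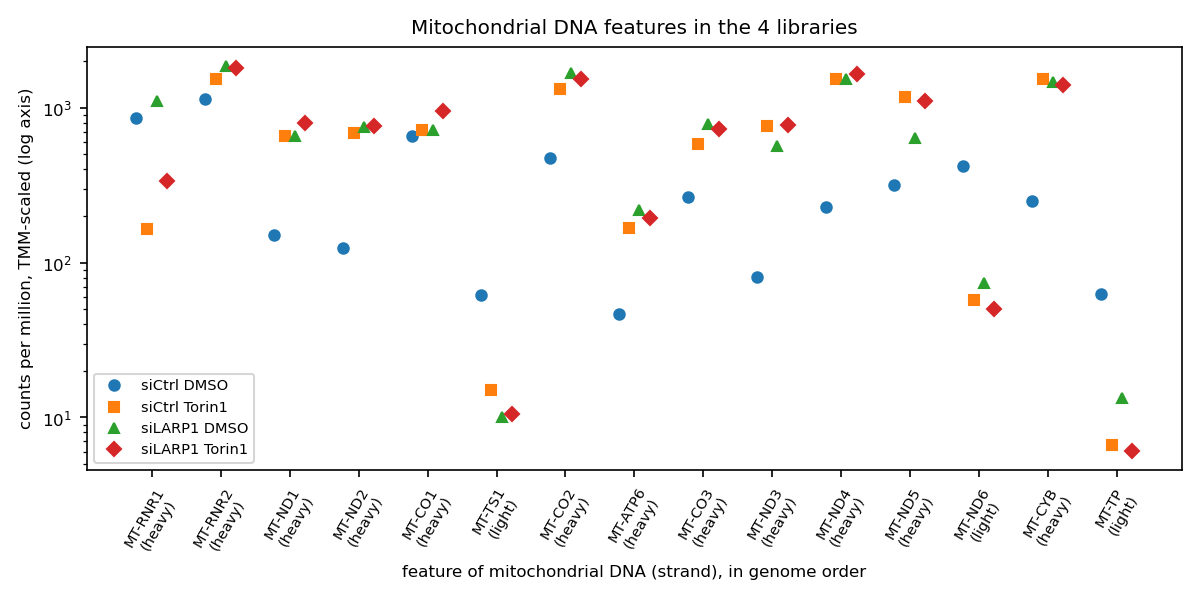
TMM-scaled CPM (y axis, log scale) of 15 features of mitochondrial DNA (x axis, in genome order, with their strand) in the 4 libraries, 1 point per library. The control-siRNA DMSO library lies lowest for all heavy-strand mRNAs, with MT-ND4 at 168 counts against 1263 to 1504, and highest for the light-strand features, with MT-ND6 at 312 counts against 45 to 69.

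Other lists showed little. Lysosome and autophagy genes had medians between -0.06 and 0.08 over the 4 comparisons and did not stand apart in any, although TPP1 rose with Torin1 (edgeR log2 1.55, adjusted p = 0.000933), as the 1 of 28 also adjusted over the list alone. S-phase genes did not stand apart (medians -0.34, -0.12, -0.09 and 0.12 for Torin1 in control siRNA, Torin1 in LARP1 siRNA, LARP1 siRNA under DMSO and LARP1 siRNA under Torin1). Of its 24 genes CCND1, cyclin D1, fell by 1.36 with Torin1 and CDC45 by 0.98 with LARP1 siRNA in edgeR (1 each adjusted over the list alone). The list of LARP relatives, cap-binding, tail-binding and mTOR pathway genes had medians between -0.02 and 0.06. In it EIF4G1, the cap complex scaffold, fell with Torin1 by 0.86 on the log2 scale (edgeR adjusted p = 0.00634), as did EIF4E (by 0.85) and EIF4EBP1 (by 1.30), 3 of 25 (4 fell and 2 rose adjusted over the list alone). Of 23 interferon response genes 2 were measured, and the list summed to 55, 68, 78 and 89 counts. None of 18 markers of other cell types was measured, and they summed to 5, 9, 8 and 9 counts, with COL1A1 the highest at 7.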

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

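The tests of explanations in this part were chosen only after the results were seen; the rule that picked single genes was set beforehand. That rule took named genes whose counting intervals lay on opposite sides of 0 in the compared arms. The difference was not tested for any of these genes, as each group holds 1 library.

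For Torin1 against DMSO, the effect in LARP1 siRNA minus that in control siRNA was 0.39 for EEF1A1 (-0.10 in control siRNA and 0.29 in LARP1 siRNA), 0.52 for EEF2 (-0.08 and 0.44), 0.56 for RPS19 (-0.14 and 0.42) and 1.16 for the snoRNA host LRRC75A-AS1 (-0.23 and 0.93). It was 0.55 for the replication factor MCM7 (-0.33 and 0.23), 0.60 for the lysosomal PSAP (-0.32 and 0.28) and 3.27 for NOP9 (-2.13 and 1.14). It was -0.76 for EIF1 (0.57 and -0.20), -1.59 for MT-CO2 (1.46 and -0.13) and -2.31 for TOB1 (1.78 and -0.53).

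For LARP1 siRNA against control siRNA, the effect under Torin1 minus that under DMSO was 2.12 for DDIT4 (-0.62 under DMSO, and 2.83-fold higher under Torin1), 2.03 for SLC2A1 (-0.75 and 1.28), 1.03 for TPI1 (-0.48 and 0.54), 0.88 for ENO1 (-0.56 and 0.32) and 0.70 for LDHA (-0.20 and 0.50). It was 0.78 for FASN (-0.34 and 0.45), 0.89 for PHGDH (-0.64 and 0.25), 0.87 for PSAT1 (-0.43 and 0.44), 1.08 for TFRC (-0.31 and 0.76) and 0.74 for MCM2 (-0.45 and 0.29). NOP9 had 3.27 here too (-1.38 and 1.89). Values below 0 were -0.47 for RPL10 (0.11 and -0.36), -0.30 for RPS2 (0.17 and -0.14), -1.18 for SNHG16 (0.53 and -0.65) and -2.68 for MT-CYB (2.54 and -0.14).

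Protein-coding TOP mRNAs had pooled medians below 0 in both LARP1 siRNA comparisons, which share no library. The small-subunit list did not stand apart from its random lists, which could hold other TOP genes. It did against random lists without TOP genes and pseudogenes, chosen after seeing the data (percentile 0.00 in both comparisons). Trends on transcript length and GC content, fitted outside TOP genes, left the median of 96 protein-coding TOP mRNAs at -0.49 (bootstrap over genes, -0.58 to -0.34) under DMSO and -0.38 (-0.41 to -0.34) under Torin1, although the first had been -0.64, so part of it went with length and GC. Trends fitted on all genes, TOP genes included, left -0.38 (-0.54 to -0.28) under DMSO, and took the large-subunit list from -0.64 (-0.82 to -0.50) to -0.33 (-0.54 to -0.27), no longer apart from random lists. Adding the counts of pseudogenes named after each gene left -0.63 (-0.77 to -0.52) under DMSO. That argues against reads lost to those pseudogenes as the whole cause. It does not cover other pseudogenes or reads that were not counted. Scaling by totals left -0.29 (-0.34 to -0.24) under Torin1, which argues against the scaling as the whole cause. A lower abundance of TOP mRNAs in LARP1-depleted cells is a candidate explanation, as a hypothesis, although the counts cover only cap-purified poly(A) RNA. Unrecorded differences between single libraries, such as the kit version, stay open.

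Of the 7 nuclear lists that stood apart below 0 with Torin1 in control siRNA, 5 stood apart above 0 for the difference of the Torin1 effects. The respiratory chain and chaperone lists (0.19 each) did not. Pooled, the 251 genes lay 0.21 above the median of matched random lists. Their distances to the central 95% of those lists ran from 0.14 to 0.27. Ranges given below beside a distance to random lists are of this kind. Picking lists by the effect that is subtracted favours this. The 6 lists that stood apart below 0 in LARP1 siRNA, a choice that works against it, lay 0.27 (0.19 to 0.35) above random lists. But these 6 are the same 7 lists without the respiratory chain. They too were low in the effect that is subtracted, so they are not a separate check. Length and GC trends taken off left the 7 lists 0.15 (0.09 to 0.22) above random lists, which argues against those trends as the whole cause, although part of it went with them. The control-siRNA DMSO library as the sole cause cannot be told apart from a difference between the Torin1 libraries (median 0.04, bootstrap over genes, -0.01 to 0.09). Between the Torin1 libraries glycolysis (0.34), ATF4 (0.24) and SREBP (0.21) genes lay above 0, and the respiratory chain (-0.14) and mitochondrial ribosome (-0.06) below. All were picked for being low with Torin1 in control siRNA. Both comparisons use the control-siRNA Torin1 library, so that choice alone favours values above 0, and these values do not decide it. Together the 6 lists lay 0.09 (0.03 to 0.16) above random lists, but 0.07 (-0.00 to 0.13) with length and GC trends taken off. A weaker action of Torin1 on all transcripts cannot be told apart either. The snoRNA host and FOXO lists had a median difference of -0.33 (bootstrap over genes, -0.62 to 0.05). The protein-coding TOP lists lay 0.08 (0.02 to 0.19) above matched random lists, but at -0.03 (-0.10 to 0.07) with trends taken off. A dependence of the response on LARP1 and a weaker or shorter Torin1 exposure of the LARP1-siRNA Torin1 culture both stay open.

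Mitochondrial mRNAs of the heavy strand were lower in the control-siRNA DMSO library than in the other 3, by a median of 2.14 on the log2 scale (bootstrap over 10 mRNAs, 1.52 to 2.67). Less carry-over of all mitochondrial RNA would lower the light-strand features as well, but their summed counts were 432 in that library against 66, 95 and 64, a log2 ratio of the other 3 over it of -2.80 (-3.04 to -2.57). MT-ND6 held most of these, with 312, 47, 69 and 45, and whether strand was used in counting is not stated. Less carry-over limited to the heavy-strand mRNAs is not covered. A loss of all transcripts up to the length of the longest of those mRNAs is argued against by 2615 nuclear genes no longer than it. Their median of the same ratio was -0.16 (-0.19 to -0.14), so that they were not lower in that library. Most of those mRNAs are shorter than that cut, and a loss limited to the shortest transcripts is not covered. A change of mitochondrial mRNA levels in the cells by Torin1 and by LARP1 siRNA cannot be told apart from a property of that 1 library, since each group holds 1 library.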

How the results depend on the processing

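No paired analysis was possible because each group holds 1 library, so no replicates pair across groups, and the blocking was by siRNA or agent in the additive model. For the same reason no library could be left out. Among the 1615 alternative values, no called list median or named-gene result changed sign. Sign changes of values never called were not counted, and counts of genes have no sign. The direction with more genes did change in some scalings. For LARP1 siRNA under DMSO, 364 genes higher and 578 lower became 793 and 294 with totals. The 80 results of named genes held in all 400 alternatives, list medians kept their side of the percentile thresholds in 1021 of 1075, and counts of genes stayed within 1.5 times in 93 of 136. Scaling alternatives shift all genes of a comparison alike, so the 85 list medians under each could not change sides. Called genes were named for lying farthest from no change, which favours their holding. Alternatives with length and GC trends taken off, pseudogenes added, random lists outside TOP genes, and counts without mitochondrial genes were chosen after seeing the data. Where a cause is not given below, the cause was not tested.

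Totals in place of TMM factors, which moved the median of all genes by 0.20 under DMSO and 0.12 under Torin1, gave 793 genes higher and 294 lower for LARP1 siRNA under DMSO, 292 and 163 under Torin1, and 69 and 33 in the additive model. No minimum fold, which lets smaller changes in, gave 497 lower for Torin1 in LARP1 siRNA, and 222 higher and 394 lower for LARP1 siRNA under Torin1. A fold of at least 2 gave 414 higher and 415 lower for Torin1 in control siRNA, 177 and 60 for Torin1 in LARP1 siRNA, 201 and 238 for LARP1 siRNA under DMSO, and 55 and 92 under Torin1. With an assumed biological coefficient of variation of 0.2 these counts were 21 and 31, 6 and 0, 9 and 15, and 0 and 1, and with 0.4 all were 0 in edgeR's exact test, so the calls rest on counting error alone. In the additive model, leaving out the covariate gave 38 higher and 43 lower for Torin1 and 0 and 0 for LARP1 siRNA (423 at an unadjusted p under 0.05 in edgeR), DESeq2 gave 9 and 36 and 0 and 31, and no filter, which tests 18846 genes, gave 195 lower for Torin1 and 25 higher for LARP1 siRNA. Correlations across genes with a mean of at least 50 counts, where counting noise is smaller, were 0.55 for the Torin1 effects and 0.38 for the LARP1 siRNA effects.

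Among the TOP lists, length and GC trends taken off left large-subunit ribosomal proteins at -0.33 for LARP1 siRNA under DMSO, no longer apart, and small-subunit ones at 0.14 for the difference of the Torin1 effects; with the trends fitted outside TOP genes the large-subunit list stood apart at -0.45, and the small-subunit difference was 0.16. A gene length trend taken off left that difference at 0.15, the list mean at 0.25 and added pseudogenes at 0.25, none of them apart. Other TOP mRNAs under Torin1 in control siRNA no longer stood apart at 0.13 with the gene length trend and 0.20 with the trends fitted outside TOP genes. Small-subunit ribosomal proteins newly stood apart for LARP1 siRNA under DMSO when thinned (-0.59) and as a mean (-0.58). Against random lists matched on gene length too, or outside TOP genes and pseudogenes, they stood apart for Torin1 in control siRNA (0.06), LARP1 siRNA under DMSO (-0.52) and under Torin1 (-0.34). Lists other than the TOP lists lost calls too. The nuclear respiratory chain lost its call for Torin1 in control siRNA with length and GC trends (-0.28) or the gene length trend (-0.24) taken off and against lists matched on gene length (-0.41), and for LARP1 siRNA under Torin1 when thinned (-0.09) or with length and GC trends taken off (-0.06). The mitochondrial ribosome lost it for LARP1 siRNA under DMSO (-0.11 with length and GC trends taken off, -0.27 against length-matched lists) and for the difference of the Torin1 effects (0.06, 0.10 with the gene length trend taken off, and 0.23 against length-matched lists). Ribosome assembly lost it for LARP1 siRNA under DMSO with a minimum of 25 counts (-0.27), no filter (-0.27), thinning (-0.26) and as a mean (-0.23). FOXO targets lost it for Torin1 in LARP1 siRNA with a minimum of 25 counts (0.29), no filter (0.34) and the gene length trend taken off (0.30), and in control siRNA with that trend taken off (0.42). Mitosis genes lost it for Torin1 in control siRNA with length and GC trends taken off (0.06). In all, 27 calls were lost and 27 gained over the 1075 alternatives. At these depths a log2 fold of 1 is mostly missed, as 25 of 97 simulated genes were recovered for Torin1 in control siRNA.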

Other observations

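The genes in this part were chosen after their values were seen. With LARP1 siRNA, some genes outside the TOP lists, picked for this, moved the same way under both agents. TBCA, a tubulin-folding cofactor, was at log2 -1.36 under DMSO and -1.38 under Torin1, and COPZ1, a vesicle coat subunit, at -1.60 and -0.99. Genes that were higher included CCND2, cyclin D2, at 1.35 and 1.38, CDKN1A, a cell cycle inhibitor, at 1.03 and 1.13, and BTG2, an antiproliferative factor, at 1.94 and 0.87. The transcription factors NFIC (1.52 and 1.66) and YY1 (0.98 and 0.76) were higher as well. In the additive model CCND2 rose by 1.37 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 7.38e-05), and TBCA fell by 1.37 (1.53e-05).

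With Torin1, a pair of amino acid transporters was lower in both siRNA arms. SLC1A3 was at log2 -2.61 in control siRNA and -1.41 in LARP1 siRNA, and SLC1A5 fell by 1.38 over both arms (edgeR adjusted p = 5.49e-06). YPEL3 was higher at 2.49 and 2.17, and HTRA1, a serine protease, at 1.87 and 1.90. CEP290, a protein of the cilium base, was at 1.92 and, from 1 to 13 counts, 3.22 (1.02 to 9.16), and IFT81 at 2.16 and 1.68.

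Protein-coding genes with at least 35% A in their transcripts (83 genes) had a median log2 ratio of -0.80 (bootstrap over genes, -1.05 to -0.63) for LARP1 siRNA under DMSO, and 1.09 (0.79 to 1.42) for Torin1 in LARP1 siRNA. For Torin1 in control siRNA the median was 0.52 (0.41 to 0.82), and for LARP1 siRNA under Torin1 -0.35 (-0.46 to -0.18). Among them, 32 genes with transcripts of at least 4000 bases had -1.59 (28 of 32 below 0) and 1.74 (31 of 32 above 0) in the first pair of comparisons, and 0.58 (0.39 to 0.93) for Torin1 in control siRNA and -0.25 (-0.51 to -0.04) for LARP1 siRNA under Torin1, while all 2274 protein-coding genes of that length had 0.13 (0.09 to 0.16), 0.03 (-0.00 to 0.05), 0.18 (0.15 to 0.21) and -0.02 (-0.03 to 0.00) in the same order. The values farthest from 0 were thus those of the comparisons that use the LARP1-siRNA DMSO library. These genes also differed in the comparisons without it, but those share the control-siRNA Torin1 library, so that this library alone favours opposite signs.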
